A study of Mus musculus with 6 samples.

How the data were processed

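RNA was measured in erythroid precursor cells of mouse fetal liver at embryonic day 14.5, from strain C57BL/6. Per the labels' protocols, cells with medium CD71 (the transferrin receptor) and no Ter119 (a surface marker of maturing red cells) were sorted, a gate named R1, and libraries were made from 10 ng of total RNA with a NuGEN Ovation single cell kit and sequenced as single reads of 50 nt. There were 3 wild type and 3 -77-/- libraries. The labels gave no litter, batch or sex, and replicates were numbered in the order of the sample records, so no replicate of one genotype was paired with a replicate of the other. The series' design text calls the samples triplicates without saying whether each came from its own embryo, so the p-values measure the spread between these samples.

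The deposited table came from the authors and held, per gene, the result of their DESeq2 comparison and a value for each of the 6 libraries. Per the submitters' processing notes, Bowtie, STAR 2.5, RSEM 1.2.31 and DESeq2 were used with the mm9 build. The roles of the 2 aligners, the DESeq2 version, the gene annotation and the strand setting were not given in the sources used here. The unit of the 6 library columns was a normalized signal that the authors made by dividing gene counts by 1 size factor per library. The values show this: within each library 100% were whole multiples of a single step, at a tolerance of 0.01 of a read, and the deposited mean per gene equalled the mean of the 6 columns. Dividing by the step gave back whole numbers, called recovered reads here. If they came from RSEM, they are expected counts rounded to whole numbers, and a 0 need not mean that no read matched the gene. The size factors read from the steps ran from 0.878 to 1.17. The log2 fold changes and adjusted p-values in the authors' deposited table were used for comparison only. In 8 of the 19444 rows, all small RNA genes, the cells were moved sideways, and these rows were left out, which left 19436 genes. Of these rows, 247 repeat a symbol that an earlier row holds; tests ran on the Ensembl gene IDs.

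The recovered reads came to between 16516338 and 20468899 per library. A count of 3 reads was taken as the floor, which corresponds to a normalized value of 2.56 to 3.42 depending on the library. Where a genotype had no read over its 3 libraries, the fold was computed against 3 reads over the group and is given as a lower bound. With 1 to 3 reads, the ratio of reads is given with an exact 95% interval. These intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

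The test was planned for counts with edgeR. Since the table held normalized values, the fallback written before the data were examined was used: limma 3.58.1 in R 4.3.3, with a trend and robust empirical Bayes, on log2(value + 1). Genes entered when their mean value was at least 10 in the higher genotype, which 15821 did. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are -77-/- over wild type on the log2(value + 1) scale, where the added 1 shrinks the change of genes with low values. They are differences between means of logs, which can exceed the ratio of means where libraries of a genotype are uneven. Hba-a1 had -5.31 here and -3.33 with DESeq2, and the median of the red cell membrane list was -4.94 here and -4.47 with DESeq2. Standard deviations are over 3 libraries. The test was checked on simulated libraries with the real means and 200 changed genes. Their spread between replicates was set by hand as a function of the mean, not estimated from the real libraries. Over 15220 genes, limma recovered 55% of 2-fold and 85% of 4-fold changes, gave all called genes the right sign, and 1.41% of its calls were false. On the same simulation edgeR recovered 56% and 88%, limma-voom 55% and 85%, and DESeq2 54% and 83%, with 0.690%, 2.78% and 7.43% of their calls false. These shares hold for the simulated spread and number of changed genes, and do not give the error rate on the real libraries.

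A total of 21 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes, on the same log2 values (log2 CPM had been planned), with adjustment over the lists. Placing genes without a read in one genotype at their bound left each list median as it was. They cover GATA factors and other erythroid transcription factors, globins, haem synthesis and iron uptake, red cell membrane and surface proteins, mitophagy and autophagy, stem and early progenitor genes, 8 lists of other cell types that the gate could hold, interferon response, innate immune receptors, both parts of the cell cycle list, p53 targets and cell cycle inhibitors, immediate early and heat shock genes, and genes flanking Gata2. Of 474 list entries, sex-linked genes included, 442 matched a row by symbol, older symbol or Ensembl ID, the last from a GRCm38 annotation that served only for names and for which genes neighbour each other. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list changed at all, whereas camera compares them with the other genes. The genes named are Gata2, the 10 largest changes in each direction among called genes with at least 5 CPM in the higher genotype and no overlap between genotypes (leaving out gene models with only a predicted or clone name), up to 4 members of each list with the smallest p, and all measured members of the flanking list; a few genes that this rule names are not reported here. Named outside this rule, after their values were seen, were Gata1, Klf1, Gfi1b, Runx1, Hba-a1, Hbb-b2, Alas2, Kit, Hoxa7, Hoxa9, Hoxb4, Csf1r, Mpo, Prtn3, Epx, S100a8, Camp, Elane, Pf4, Itga2b, Ebf1, Pax5, Rag1, Fos, Jun, Hspa1a, Prg3, Ear6, Ncl, Npm1, Zbtb46, Nfkbia, Slc2a1, Ftl1, Slc25a39, Kif23, Aen, Gadd45a, Sesn2, Hsph1, Hspa8, Mmp8, Hp, Gnl3, Nop58, Bop1, Cd55, Ear2, Il5ra, Gp5, Treml1 and F5, and, with values only, Xist, Alb, Afp, Trim10, C1qb, C1qc, Mrc1, Cd163, Vcam1 and Marco.

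Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, and edgeR 4.0.16 with DESeq2 size factors or upper-quartile scaling, all on the recovered reads; limma with no filter, with at least 5 CPM in 3 libraries, with a pseudocount of 0.1 or 5, or with a threshold of 2-fold; and each library left out in turn. Chosen after seeing the data were edgeR with TMM on the recovered reads, which called 4745 genes, and limma with TMM scaling. Reads of near-identical genes can be split by the counting step, so values of the globin pairs Hba-a1 and Hba-a2 and Hbb-b1 and Hbb-b2, of the Oas, Gbp, Ms4a6 and Ear families, and of the pseudogene Psme2b-ps are uncertain. Without a stated strand setting, genes that overlap on opposite strands cannot be told apart either.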

Results

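The transcriptomes of CD71-medium, Ter119-negative erythroid precursors from E14.5 mouse fetal liver were compared between wild type embryos and embryos labelled -77-/-. The -77 element is an enhancer upstream of Gata2, which encodes a transcription factor of blood stem and progenitor cells; -77-/- denotes its loss from both alleles. The comparison asks how gene expression in the sorted precursors differs when the element is missing. Each genotype had 3 libraries. Recovered reads came to 19840113, 18478251 and 16516338 in wild type replicates 1 to 3 and to 17914866, 17445889 and 20468899 in -77-/- replicates 1 to 3. Between 14847 and 18133 genes had at least 1 read. Mitochondrial ribosomal RNA took 9.70%, 7.95% and 7.98% of reads in wild type replicates 1 to 3 and 7.86%, 7.20% and 6.43% in -77-/- replicates 1 to 3, without overlap, as chance gives in 10% of such comparisons. On log2 values, Pearson's r across genes, which are not independent replicates, was 0.880 to 0.939 within a genotype and 0.790 to 0.853 between genotypes. The first principal component held 50.6% of the variance and separated the genotypes. As a check for a library deposited in duplicate, counts were compared in pairs against counting error alone, and the smallest chi-square per degree of freedom was 18.3, so no pair was treated as 1 library. Wild type replicate 2 alone expressed Xist, at 41877 normalized reads against 28.5 to 63.2 in the other 5 libraries, so all 3 -77-/- libraries and the other 2 wild type libraries had the expression of males.

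Gata2 itself (ENSMUSG00000015053) was low in both genotypes and did not pass the test. Its normalized read counts were 128, 87.8 and 61.5 in wild type replicates 1 to 3 and 74.2, 26.2 and 34.2 in -77-/- replicates 1 to 3. The means were 92.3 ± 33.3 and 44.9 ± 25.7 (SD, n = 3 here and throughout), a log2 fold change of -1.10 (SE 0.60, limma adjusted p = 0.183). The genotypes overlapped, and at 278 and 140 reads in all the difference was not resolved from the replicate spread. In the authors' deposited table the log2 fold change of Gata2 was -1.04 with an adjusted p of 0.226. Of 13 measured genes flanking Gata2, 1 was higher, 5 were lower and 7 did not pass, with the same counts adjusted over the list alone. Mgll, a monoacylglycerol lipase, fell from 157 ± 31.4 to 5.07 ± 4.74 (log2 fold change -5.24, SE 0.99, limma adjusted p = 8.3e-04). Ruvbl1, Isy1 and Cnbp had log2 fold changes of -0.62, -0.59 and -0.50, and 8430410A17Rik fell from 289 ± 15.6 to 144 ± 19.3. Sec61a1, a subunit of the protein translocation channel, rose by 0.60 on the log2 scale. The remaining members had log2 fold changes of 0.16 for Rpn1, 0.16 for Rab7, 0.07 for Copg, -0.02 for Rab43, -0.41 for Eefsec, 0.74 for Abtb1 and 2.35 for H1fx. Leaving out each library in turn gave 0.32 to 1.11 for Abtb1, -0.52 to -0.22 for Eefsec, 0.006 to 0.16 for Copg and 0.08 to 0.26 for Rab7. As a group the list did not change (median log2 fold change -0.02, camera adjusted p = 0.302). The call of 8430410A17Rik ended without wild type replicate 1 (limma adjusted p = 0.0505) and without -77-/- replicate 2 (0.0513), with a range of 0.0089 to 0.0513 over its alternatives.

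Across the transcriptome, 5091 of 15821 tested genes differed, 2681 higher and 2410 lower in -77-/-. At least 2-fold changes made up 1988 of the higher and 967 of the lower genes. In 5021 of the 5091 the 3 libraries of one genotype did not overlap those of the other, against 7350 of all tested genes, where chance gives 10%. The median log2 fold change of all tested genes was 0.10. The authors' deposited table called 5324 genes, 2805 higher and 2519 lower, among 17124 with an adjusted p. Of the calls made here, 4941 (97.1%) were among them, all in the same direction.

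Among the largest increases were interferon-inducible and innate immune genes. Psme2b-ps, a proteasome activator pseudogene, and Fam83f had no read in wild type and means of 212 ± 100.1 and 147 ± 52.8 in -77-/-, at least 225-fold and at least 152-fold higher. Mx2, an interferon-induced GTPase, had 1 read in wild type and 708 in -77-/-, a ratio of 695 (95% interval 124 to 27504). The ratios for the antiviral synthetase Oas2, the endosomal receptor Tlr8 and the phosphatase Dusp22, with 2, 1 and 3 wild type reads, were 361 (99.6 to 2986), 430 (76.8 to 17030) and 240 (81.8 to 1166). Ms4a6b, Ifi204, Rgs3 and Gbp3 rose by 7.05, 6.88, 6.76 and 6.68 on the log2 scale. The call of Ifi204 ended with a pseudocount of 0.1 (limma adjusted p = 0.0558, range 1.2e-07 to 0.0558 over its alternatives). Among the largest decreases, Aqp1, the red cell water channel, fell from 1264 ± 172 to 13.2 ± 6.26, and Fam55b from 1993 ± 168 to 24.5 ± 16.6. Gjb2, a gap junction protein, fell from 840 reads to 1, a ratio of 855 (153 to 33820). Prss50, Arhgdig, Acsl6, Myh7b and Gstm5 had log2 fold changes of -7.37, -6.90, -6.82, -6.58 and -6.48. Ear1, an eosinophil ribonuclease, had 412 reads in wild type and 2 in -77-/-, a ratio of 210 (57.7 to 1738).

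**Figure D1:**
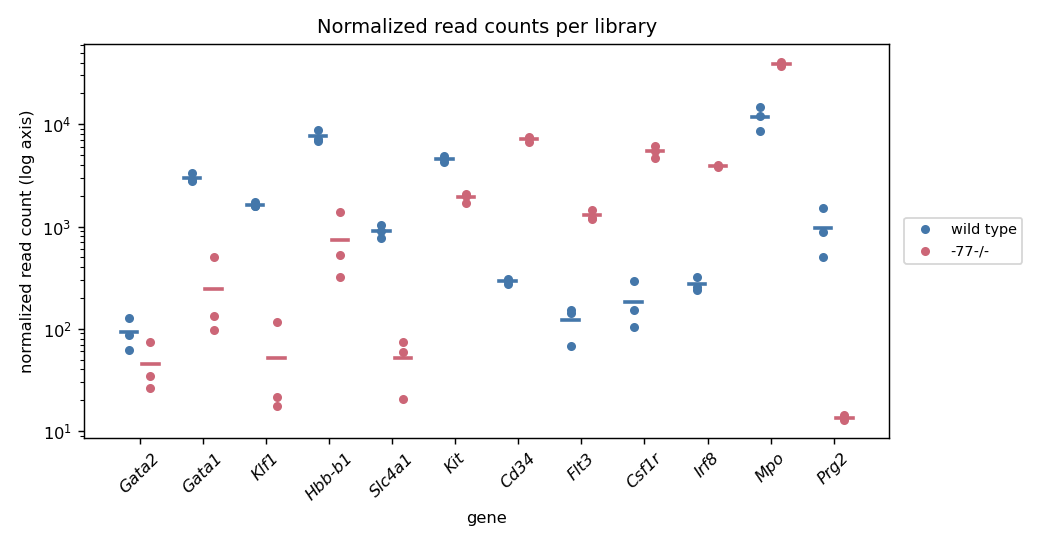
Normalized read counts (log axis) of 12 genes in the 3 wild type (blue) and 3 -77-/- (red) libraries; each point is a library and each bar the mean of its genotype. Gata2 overlaps between genotypes, while Gata1 lies between 96.2 and 502 in -77-/- against 2805 to 3358 in wild type, and Csf1r between 4712 and 6103 against 104 to 293.

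Erythroid genes were lower in -77-/- across all 4 lists that describe red cell development. Of 20 erythroid transcription factors, 15 were lower and 1 higher, also adjusted over the list alone. Gata1, the main GATA factor of red cell maturation, fell from 3012 ± 302 to 244 ± 225 (log2 fold change -4.01, SE 0.69, limma adjusted p = 0.0125). Its cofactor Zfpm1 fell from 1584 ± 47.6 to 110 ± 29.1, its partner Tal1 from 3955 ± 178 to 525 ± 163, and Klf1, an activator of globin genes, from 1637 ± 93.4 to 51.9 ± 56.3. Gfi1b, Ldb1 and Bcl11a had log2 fold changes of -4.43, -1.62 and -1.37, and Runx1, a factor of stem and progenitor cells, was the member that rose, from 1069 ± 228 to 3069 ± 224. The list had a median log2 fold change of -1.08 (camera adjusted p = 4.5e-08, and adjusted p = 0.128 with an estimated correlation). Red cell membrane and surface genes showed the lowest median, -4.94, with 25 of 26 members lower, also over the list alone. Slc4a1, the anion exchanger band 3, fell from 905 ± 125 to 51.2 ± 27.7, Kel, a blood group antigen, from 965 ± 93.4 to 30.1 ± 20.6, and Tspo2 from 785 ± 15.5 to 60.04 ± 24.2 (camera adjusted p = 3.2e-18, and adjusted p = 0.125 with an estimated correlation). Slc2a1, a glucose transporter, was the member that did not pass, at 1084 ± 16.1 and 1071 ± 106. In -77-/- replicate 1 Gata1 stood at 502 against 96.2 and 132 in replicates 2 and 3, and Klf1 at 117 against 17.5 and 21.3, whereas Aqp1 was lowest there, at 6.10 against 15.6 and 17.9. Without -77-/- replicate 3 the call of Gata1 ended (limma adjusted p = 0.0585, range 6.6e-08 to 0.0585 over its alternatives), at a log2 fold change of -3.76.

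Haem synthesis and iron uptake genes fell in 18 of 20 cases, also over the list alone, with a median log2 fold change of -2.24 (camera adjusted p = 3.1e-14, and adjusted p = 0.106 with an estimated correlation). Fech, the enzyme that inserts iron to form haem, fell from 3108 ± 259 to 595 ± 123, the iron reductase Steap3 from 2236 ± 49.0 to 369 ± 90.9, and the iron transporter Slc11a2 from 1808 ± 178 to 254 ± 87.3. Alas2, the erythroid enzyme that starts haem synthesis, fell from 207 ± 41.0 to 17.6 ± 14.7. Ftl1 and Slc25a39 did not pass, with log2 fold changes of 0.18 and 0.27, or 0.08 and 0.10 without wild type replicate 1. Among 6 measured globin genes 2 were lower, or 3 adjusted over the list alone, and 4 did not pass. Hba-a2 fell from 1595 ± 119 to 93.6 ± 21.9 and Hbb-b1 from 7639 ± 1042 to 744 ± 561. Hbb-b2 had 4997 ± 2494 and 479 ± 463 (limma adjusted p = 0.0528) and Hba-a1 had 917 ± 175 and 91.4 ± 115 (limma adjusted p = 0.167). The globin list had a median of -3.72 (camera adjusted p = 0.0027, and adjusted p = 0.146 with an estimated correlation). The call of Hbb-b1 ended without -77-/- replicate 3 (limma adjusted p = 0.0589, range 2.2e-07 to 0.0589 over its alternatives). Hbb-b2 passed with DESeq2 (adjusted p = 0.0010), limma-voom (0.0430), at 5 CPM (0.0388) and without -77-/- replicate 1 (0.0199), with a range of 0.0010 to 0.146 over its alternatives. Hba-a1 passed with limma-voom (adjusted p = 0.0332) and without -77-/- replicate 3 (0.0066, log2 fold change -3.05), with a range of 0.0066 to 0.292. Mitophagy and autophagy genes did not change as a list (median -0.03, camera adjusted p = 0.867): Wipi1 and Bnip3l, a mitophagy receptor of red cell maturation, had log2 fold changes of -3.04 and -0.81, Map1lc3b rose by 0.64, and 11 of 14 did not pass. The call of Map1lc3b ended without wild type replicate 2 (limma adjusted p = 0.0772) and without -77-/- replicates 1 and 3 (0.0724 and 0.0572; range 0.0091 to 0.0772).

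**Figure D2:**
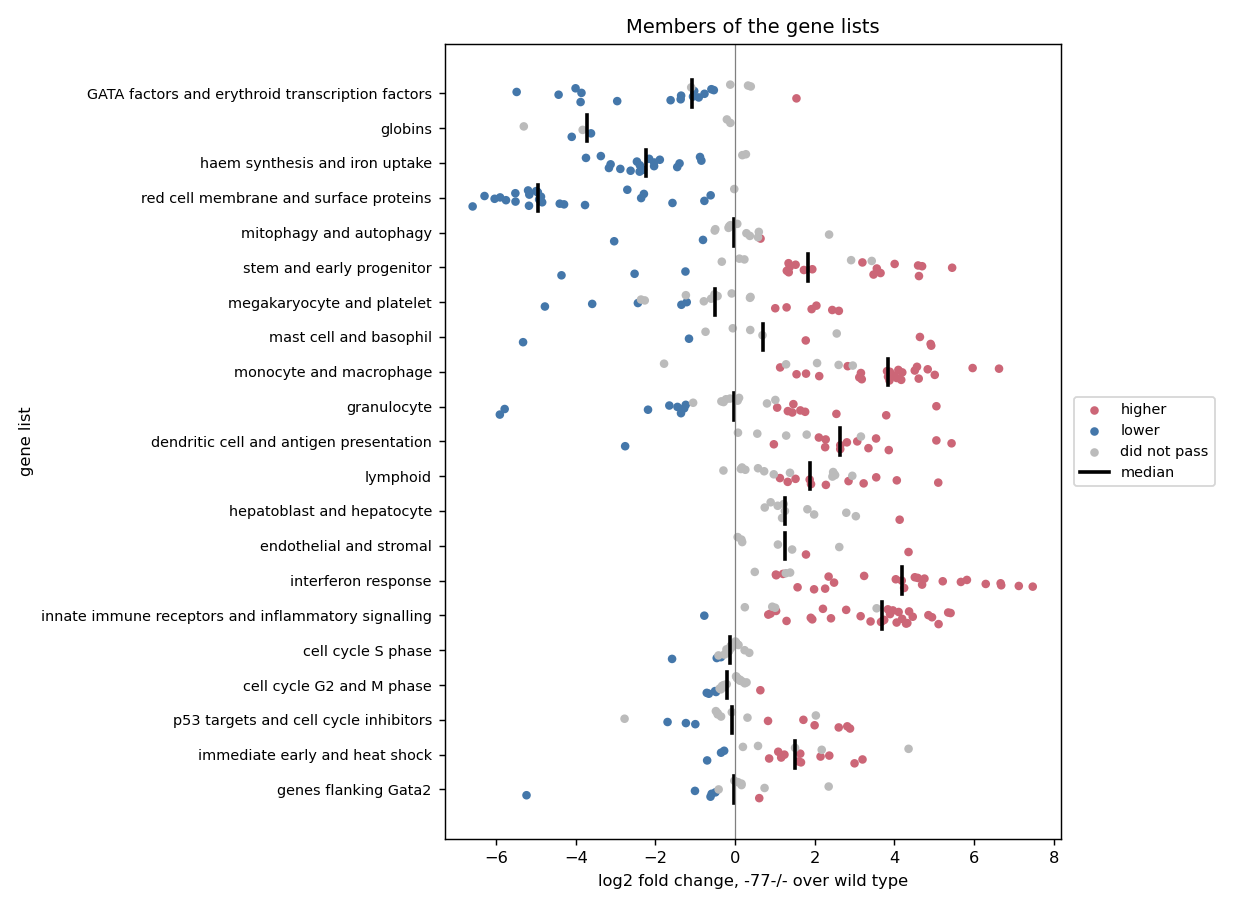
Log2 fold changes (-77-/- over wild type) of the measured members of the 21 gene lists; each point is a gene, red where higher, blue where lower and grey where it did not pass, and each black bar is the median of its list. Red cell membrane genes have a median of -4.94, monocyte and macrophage genes 3.84 and interferon response genes 4.18.

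Stem and early progenitor genes were mostly higher: of 24 measured, 16 rose, 3 fell and 5 did not pass, or 17 and 4 adjusted over the list alone. Cd34, a surface protein of progenitors, rose from 291 ± 18.7 to 7138 ± 423 (log2 fold change 4.61, SE 0.13, limma adjusted p = 1.9e-11), and Flt3, a receptor of early lymphoid and myeloid progenitors, from 121 ± 46.5 to 1283 ± 155. The 3 that fell were Samd14, from 1512 ± 141 to 79.0 ± 42.0, Mllt3, from 1422 ± 375 to 243 ± 46.8, and Kit, the stem cell factor receptor, from 4596 ± 318 to 1939 ± 202. The Hox genes Hoxa7, Hoxa9 and Hoxb4 were among those that rose, at low levels, but the call of Hoxa9 ended in 4 alternatives and that of Hoxb4 in 11 (adjusted p from 0.0029 to 0.109 and from 0.0161 to 0.159 over the limma, edgeR and DESeq2 settings). The list median was 1.83 (camera adjusted p = 2.9e-04, and adjusted p = 0.125 with an estimated correlation).

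Monocyte and macrophage genes rose in 24 of 29 cases and none fell, also adjusted over the list alone. Csf1r, the receptor for macrophage colony-stimulating factor, rose from 183 ± 98.4 to 5423 ± 696 (log2 fold change 5.01, SE 0.36, limma adjusted p = 3.9e-05). Ccr2, a chemokine receptor of monocytes, rose from 232 ± 76.1 to 5469 ± 571, the pore-forming Mpeg1 from 290 ± 68.5 to 4202 ± 599, Ms4a6c from 137 ± 19.9 to 2488 ± 425, and Tyrobp, a signalling adaptor, from 164 ± 36.3 to 1468 ± 102. The list median was 3.84 (camera adjusted p = 3.1e-14, and adjusted p = 0.1003 with an estimated correlation). Dendritic cell and antigen presentation genes were higher in 13 of 19 cases and lower in 1, or 15 and 1 adjusted over the list alone. Irf8, a transcription factor of monocyte and dendritic lineages, rose from 272 ± 41.7 to 3923 ± 101, and Runx2, the class II chaperone Cd74 and Bst2 rose by 2.64, 3.35 and 2.26 on the log2 scale. The member that fell was Zbtb46, a transcription factor of dendritic cells and red cell precursors, from 470.01 ± 50.02 to 69.5 ± 16.7. That list had a median of 2.64 (camera adjusted p = 1.2e-05, and adjusted p = 0.1003 with an estimated correlation).

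Granulocyte genes moved in both directions, 9 higher and 8 lower of 26, or 10 and 8 adjusted over the list alone. Camera found no shift of the list in 1 direction (median -0.03, mean -0.03, camera adjusted p = 0.867, with a test direction upward). Among those higher, the myeloid transcription factor Cebpa rose from 93.4 ± 21.0 to 1289 ± 120, the granulocyte colony-stimulating factor receptor Csf3r from 213 ± 78.0 to 1185 ± 52.1, and the granule enzymes Mpo, from 11805 ± 3123 to 38959 ± 1865, and Prtn3, from 806 ± 247 to 2109.6 ± 90.2. Mmp8, a neutrophil collagenase, and Hp, haptoglobin, rose by 5.05 and 1.46 on the log2 scale, the call of Hp ending without -77-/- replicate 2 (limma adjusted p = 0.0567, range 3.8e-04 to 0.0567). Without wild type replicate 2 the log2 fold change of Hp was 0.96. Among those lower, S100a9 fell from 2390 ± 148 to 941 ± 174, and S100a8 and Camp, a granule peptide, had log2 fold changes of -1.45 and -2.19. Prg2, the eosinophil major basic protein, fell from 962 ± 510 to 13.6 ± 0.716, and its call ended with limma-voom (adjusted p = 0.0666, range 2.8e-48 to 0.0666 over its alternatives). The neutrophil elastase gene Elane did not pass, at 804 ± 372 and 673 ± 103, except that it did without wild type replicate 2 (limma adjusted p = 0.0314, range 0.0314 to 0.971), the library with the lowest value.

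Interferon response genes were higher in 24 of 27 cases and none was lower, or 25 higher adjusted over the list alone (median 4.18, camera adjusted p = 2.9e-10, and adjusted p = 0.136 with an estimated correlation). Irf1, an interferon-induced transcription factor, rose from 279 ± 12.3 to 831 ± 104, Oasl2 from 36.9 ± 29.7 to 591 ± 96.5, and Bst2, which the dendritic cell list also holds, from 177 ± 33.6 to 840 ± 34.1. Innate immune receptors and inflammatory signalling genes were higher in 29 of 34 cases and lower in 1, or 31 and 1 adjusted over the list alone. Clec7a, a receptor for fungal glucans, rose from 77.03 ± 22.2 to 2632 ± 298, Tlr2 from 43.3 ± 8.30 to 733 ± 116, Il6ra from 93.9 ± 27.6 to 1816 ± 206 and Cd180 from 51.3 ± 17.3 to 1006 ± 75.4. The member that fell was Nfkbia, an inhibitor of NF-kappaB, from 1573 ± 225 to 917 ± 102. The median was 3.69 (camera adjusted p = 1.4e-12, and adjusted p = 0.0832 with an estimated correlation). The monocyte list rose in the same libraries, as any list that rises with genotype does, so no link between these rises was shown.

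Lists of other cells that the gate could hold moved less evenly. Lymphoid genes were higher in 11 of 24 cases and none was lower, or 13 higher adjusted over the list alone (median 1.89, camera adjusted p = 7.2e-04, and adjusted p = 0.287 with an estimated correlation). Ighm rose from 386 ± 147 to 1849 ± 569.5, Cd79b from 96.4 ± 77.7 to 711 ± 12.0, and Blnk and Gata3 by 1.90 and 5.10 on the log2 scale. Part of the list was highest in -77-/- replicate 1: Ebf1 stood at 749 there against 235 and 318 in replicates 2 and 3, and Rag1 at 796 against 377 and 439. Without that replicate the calls of Ebf1, Pax5 and Rag1 ended (limma adjusted p = 0.159, 0.137 and 0.0554; ranges 0.0068 to 0.159, 0.0134 to 0.137 and 0.0017 to 0.0554), and the log2 fold change of Ebf1 went from 1.12 to 0.64. The call of Ebf1 also ended with limma-voom (adjusted p = 0.0780) and without wild type replicates 1, 2 and 3 (limma adjusted p = 0.0578, 0.0738 and 0.112), and that of Pax5 without -77-/- replicates 2 and 3 (0.0655 and 0.0514). Megakaryocyte and platelet genes split, 6 higher and 5 lower of 21 (the same over the list alone), with a median of -0.52, a mean of -0.46 and a test direction upward (camera adjusted p = 0.867). The median lay between -0.83 and -0.18 when 1 library was left out. Those that rose, Fli1, Plek, Nbeal2 and Thbs1 among them, are also active in other blood cells, whereas Pf4, a platelet granule chemokine, went from 100.2 ± 39.1 to 20.6 ± 14.4 and the integrin Itga2b from 195 ± 52.5 to 82.0 ± 16.4. The calls of Pf4 and Itga2b each ended without wild type replicate 2 or 3 (limma adjusted p = 0.0836 and 0.0701, and 0.104 and 0.0613), that of Pf4 also without -77-/- replicate 2 (0.0847) and that of Itga2b without -77-/- replicates 1 and 3 (0.0650 and 0.0765). The ranges over the alternatives were 0.0097 to 0.0847 for Pf4 and 0.0181 to 0.104 for Itga2b. Treml1, F5 and Gp5 were the other lower members, with log2 fold changes of -4.78, -1.35 and -3.59. Treml1 and F5 passed under every limma, edgeR and DESeq2 alternative that tested them, with adjusted p at most 0.0449 and 0.0464. The call of Gp5 ended in several, with a range of 0.0081 to 0.0986. Mast cell and basophil genes did not change as a list by camera, with 4 higher and 2 lower of 11, or 5 and 2 over the list alone (median 0.69, camera adjusted p = 0.169). The list passed camera with DESeq2 (median 1.02, camera adjusted p = 0.0248), and fry called it upward (fry adjusted p = 0.0015). Over the other tools, scalings, filters, pseudocounts and left-out libraries the camera adjusted p ran from 0.0248 to 0.271. At 5 CPM the median was 1.23. The chemokine Ccl3 and Ifitm1, which other blood cells also express, rose by 4.92 and 4.91 on the log2 scale and Mitf by 1.77, while Il1rl1, a receptor of mast cells, fell by 5.32, a call that ended with a pseudocount of 0.1 (limma adjusted p = 0.0615, range 3.0e-05 to 0.0615). Of 11 hepatocyte genes Trf alone rose, from 21.4 ± 21.1 to 268 ± 119 (list median 1.25, camera adjusted p = 0.138). Of 8 endothelial and stromal genes Pecam1 rose from 138 ± 53.7 to 449 ± 34.7 and Pdgfrb from 4.75 ± 6.36 to 72.2 ± 20.5 (list median 1.25, camera adjusted p = 0.177, fry adjusted p = 0.0261). That median was 0.28 to 0.29 with DESeq2, which tested 13 members, and with edgeR under 3 scalings, which tested 9. Both counts were the same adjusted over the list alone. The call of Pdgfrb ended without -77-/- replicate 2 (limma adjusted p = 0.0579, range 9.6e-04 to 0.0579).

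Cell cycle genes differed little. Of 21 S phase genes 4 were lower and none higher, or 3 lower adjusted over the list alone: cyclin E1 (Ccne1) fell from 2738 ± 245 to 927 ± 208, and Rrm1, Slbp and Cdc6 had log2 fold changes of -0.46, -0.36 and -0.38. The list passed narrowly (median -0.12, camera adjusted p = 0.0354, and adjusted p = 0.462 with an estimated correlation), and its call ended with DESeq2 (0.058), with edgeR and DESeq2 size factors (0.0548), at 5 CPM (0.131), without wild type replicate 2 (0.0689) or 3 (0.0802) and without -77-/- replicate 2 (0.0867), with a range of 0.0102 to 0.131. The calls of Slbp and Cdc6 ended without wild type replicate 2 (limma adjusted p = 0.0837 and 0.0983) and -77-/- replicate 1 (0.057 and 0.101), and that of Cdc6 also without wild type replicate 3 (0.0943), -77-/- replicate 2 (0.090) and -77-/- replicate 3 (0.0556). Their ranges were 0.0054 to 0.0837 and 0.0245 to 0.101. Of 21 G2 and M phase genes 4 were lower and 1 higher, also over the list alone, with log2 fold changes of -0.66, -0.71, -0.48 and -0.51 for Hmmr, Ccna2, Mki67 and Ccnb1 and 0.63 for Kif23 (list median -0.21, camera adjusted p = 0.102). Fry called this list downward (fry adjusted p = 0.0347). Among 17 p53 targets and cell cycle inhibitors 6 rose and 3 fell, also over the list alone. The inhibitor Cdkn1a rose from 69.9 ± 17.3 to 420 ± 15.2, the cell death gene Pmaip1 from 386 ± 76.2 to 2828 ± 232, and Trp53inp1 and Btg2 by 2.81 and 1.99 on the log2 scale, while Aen fell from 1096 ± 216 to 542 ± 60.6 and Gadd45a and Sesn2 had log2 fold changes of -1.24 and -1.70. By camera that list did not shift in 1 direction (median -0.08, mean 0.39, camera adjusted p = 0.590, with a test direction upward). Fry called it upward (fry adjusted p = 0.0123). Immediate early and heat shock genes rose in 11 of 19 cases and fell in 3, or 13 and 3 adjusted over the list alone (median 1.504, camera adjusted p = 2.8e-05, and adjusted p = 0.306 with an estimated correlation). Zfp36, which destabilises inflammatory messenger RNA, rose from 661 ± 138 to 5238 ± 700, Dusp1 from 1301 ± 83.5 to 3933 ± 523, Fos from 3105 ± 926 to 9438 ± 1922, Jun from 5449 ± 733 to 9793 ± 568 and Hspa1b from 3680 ± 546 to 11489 ± 147, while the chaperone Hsp90aa1 fell from 77286 ± 2632 to 47673 ± 5515. Hsph1 and Hspa8 were the other members that fell, with log2 fold changes of -0.35 and -0.28, and the call of Hspa8 ended with edgeR and DESeq2 size factors (adjusted p = 0.0564) and without wild type replicate 1 or 2 or -77-/- replicate 2 or 3 (limma adjusted p = 0.0516, 0.114, 0.0508 and 0.107; range 0.0035 to 0.114).

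**Figure D3:**
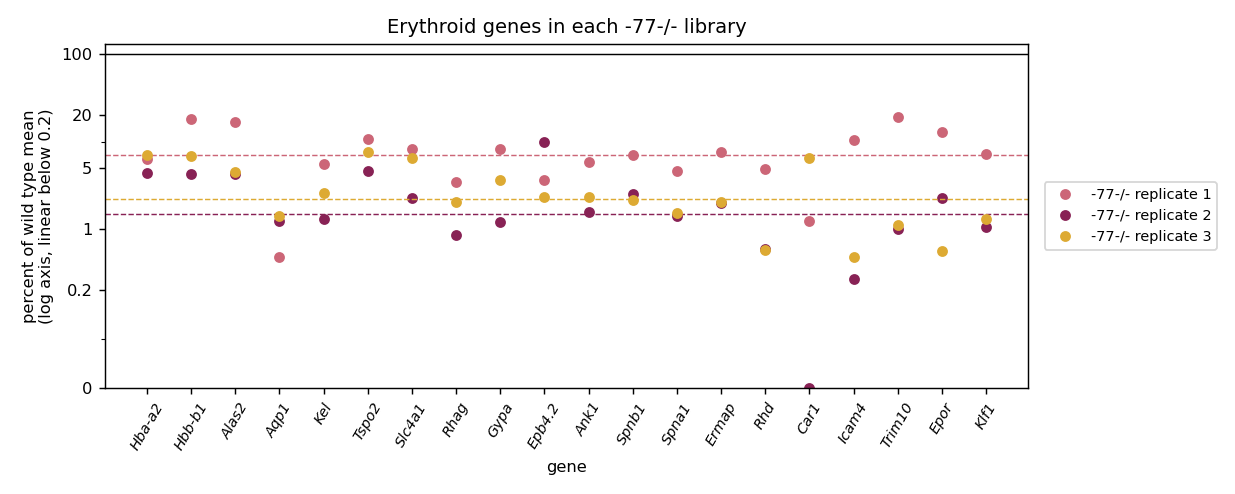
Values of 20 erythroid-restricted genes in each -77-/- library as a percent of their wild type mean (log axis, linear below 0.2); points are libraries, dashed lines their medians and the black line the wild type mean. The medians were 7.11%, 1.48% and 2.23% in -77-/- replicates 1, 2 and 3.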

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

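EdgeR and limma with TMM were chosen after seeing the data. The number of differing genes ran from 3915 to 5280 over the 10 other tools, scalings, filters and pseudocounts and the 6 settings that leave out a library, and shared calls kept their direction in each of them; 75.7% to 99.7% of the calls were kept. The median log2 fold change of all genes lay between -0.05 and 0.11. Counts moved by over 1.5 times at a threshold of 2-fold, by construction, with 2955 differing and 967 lower genes. With an estimated correlation camera called 0 of the 21 lists, while 7 had an unadjusted p under 0.05 and fry called 16. Fry called the mast cell (adjusted p = 0.0015), p53 (0.0123), endothelial and stromal (0.0261) and G2 and M phase (0.0347) lists, which camera at the preset correlation did not. Fry's test for changes in either direction passed for every list, with adjusted p at most 0.0157. Fry does not compare a list with the other genes. With 5091 of 15821 genes called, a list can pass fry without standing out, so its calls add no support to those of camera. Gata2 passed under no alternative, with adjusted p from 0.0878 to 0.409. The median of the p53 list was above 0 with DESeq2 (0.037), edgeR with DESeq2 size factors (0.146), upper-quartile scaling (0.133) and TMM (0.147). That of the genes flanking Gata2 was above 0 with DESeq2 (0.021) and no filter (0.027), and that of the megakaryocyte list at 5 CPM (0.386). Leaving out each library gave -0.20 to 0.11 for Rab43, -0.072 to 0.062 for Slc2a1, -0.61 to 0.12 for Elane, -0.36 to 0.30 for the granulocyte list, -0.13 to 0.27 for the p53 list, -0.26 to 0.12 for the flanking list and -0.12 to 0.10 for the mitophagy list. None of these passed limma or camera with all 6 libraries, though fry called the p53 list. The cause of these reversals was not tested. Without each library the S phase median ran from -0.18 to -0.06, the megakaryocyte median from -0.83 to -0.18, the mast cell median from 0.39 to 0.90 and the hepatocyte median from 1.16 to 2.01. By camera, the mast cell list passed with DESeq2 (adjusted p = 0.0248), the G2 and M phase list without -77-/- replicate 1 (0.0456) and the hepatocyte list without -77-/- replicate 2 (0.0464). Hoxb4 lost its call in 11 settings and Hoxa9 in 4. A sex term was planned only if both genotypes held both sexes and was not run, as the -77-/- libraries were all male. With 1 female library it would give the fold changes of the fit without that library, wild type replicate 2. Values under about 3 reads per library are not resolved at this depth.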

Other observations

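The tests on dilution, size factors, mature macrophages, unchanged proportions, sex and handling were written after the results they bear on were seen; those on other splits, neighbouring genes and the eosinophil, ribosome biogenesis and Hox genes were written before.

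Genes of ribosome production were lower in -77-/-. Ncl and Npm1, abundant nucleolar proteins, fell from 79848 ± 6486 to 41945 ± 6013 and from 66408 ± 4451 to 39214 ± 3921 normalized reads (SD, n = 3). They were noticed in the data, and a list of 24 other ribosome biogenesis genes was then written without looking at their values. Among the 23 measured, 22 were lower and none higher, with a median log2 fold change of -0.78 (camera adjusted p = 1.3e-12 over the 3 lists described here, and adjusted p = 0.329 with an estimated correlation). With edgeR under 3 scalings, with limma under TMM and without each library, 21 or 22 were lower and the median ran from -0.84 to -0.68. Gnl3, a nucleolar GTPase, fell from 3697 ± 115 to 1347 ± 233, and Nop58, a core protein of small nucleolar particles, from 9212 ± 673 to 4579 ± 721. Bop1 did not pass, at 1853 ± 346 and 1505 ± 399, and 1 of the 24 was not measured. A change in which cells were sorted was not separated from a change within cells.

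Some eosinophil granule protein genes, picked after their values were seen, were lower in -77-/-: besides Prg2 and Ear1, Epx went from 249 ± 117 to 6.73 ± 9.25, Prg3 from 421 reads to 4 and Ear6 from 446 reads to 5. Of 10 other eosinophil genes, 5 were measured. They did not pass as a set (median -1.42, camera adjusted p = 0.325), and the median was -0.34 without -77-/- replicate 1 and -2.27 without -77-/- replicate 2. Among them Cd55, which is not restricted to eosinophils, fell from 708 ± 208 to 48.7 ± 18.4, Ear2 from 142 ± 139 to 17.7 ± 18.7, and the interleukin 5 receptor gene Il5ra rose from 108 ± 60.9 to 231 ± 42.7. The calls of Ear2 and Il5ra each ended in 9 alternatives (limma-voom adjusted p = 0.170 for Ear2, limma adjusted p = 0.158 for Il5ra without -77-/- replicate 2; ranges 0.0042 to 0.170 and 0.0208 to 0.158). The log2 fold change of Il5ra went from 1.27 to 0.73 without wild type replicate 2. Hoxa7, Hoxa9 and Hoxb4 were higher at low levels, with means of 106, 53.3 and 32.1 against 4.205, 3.28 and 2.83, and the calls of Hoxa9 and Hoxb4 ended in 4 and 11 alternatives (adjusted p from 0.0029 to 0.109 and from 0.0161 to 0.159 over the limma, edgeR and DESeq2 settings). Of 15 other Hox genes, 2 were measured and neither passed. Their median was 1.133 (camera adjusted p = 0.745). It was 0.13 to 2.47 when 1 library was left out, and edgeR, which tested 1 of them, gave -0.14, -0.14 and -0.13 under 3 scalings. Whether other Hox genes rise stays open.

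For the number of differing genes, the real grouping gave 5091 and the highest of the other 9 groupings of 3 against 3 gave 0. Each of those 9 mixed the genotypes within both groups. A genotype difference then widens the spread within groups, so a low count was to be foreseen. The count of groupings with as many was 1 of 10, and 10 groupings are too few for a share under 0.05, so the comparison decides nothing.

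The fall of erythroid genes may reflect fewer wild-type-like erythroid cells in the sorted population, or lower expression within cells. If wild-type-like cells were diluted, erythroid-restricted genes would stand at about 1 share of their wild type mean in a library, but the SD of the log2 shares over 20 genes was at least 1.163 in the -77-/- libraries against at most 0.219 in the wild type libraries. In replicate 1, for example, Aqp1 stood at 0.483% and Trim10 at 19.2%. The SDs of the genotypes are not on a par. Each wild type library is part of the mean it was set against, which narrows its SD. Low counts widen the SD in -77-/-, where Car1 stood at 0% in replicate 2. The counting interval left out the median share for 14, 10 and 13 of 20 genes in replicates 1, 2 and 3, while the bound set for this test asked for more than 10 in each replicate and replicate 2 had 10, so dilution and lower expression cannot be told apart by it. The fall held under each scaling tried, as the median of the red cell membrane list was at most -4.466 under upper-quartile and TMM scaling. The authors' size factors ran only from 0.878 to 1.17, so such a change of scaling could hardly remove a fall of this size. A change of total RNA per cell was not tested.

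The rise of monocyte and macrophage genes was weighed against 3 explanations. Mature tissue macrophages are argued against: over 6 of 9 listed genes that had a row, C1qb, Mrc1 and Cd163 among them, the median was at most 0.2269% of the Csf1r level in any -77-/- library, with C1qb at 10.9 ± 8.59 and Mrc1, the highest, at 49.997 ± 5.01. A loss of erythroid cells with the other cells in unchanged proportions would raise other lineages alike. However, the upper quartile was 1.007 for the megakaryocyte list and 1.41 for the granulocyte list, whose median was -0.03. The lower quartile of the monocyte list was 2.60 and its median 3.84. The libraries do not show which cells held the megakaryocyte and granulocyte transcripts in wild type. If erythroid precursors held part of them, their loss would lower those lists too. The uneven rise therefore argues against unchanged proportions only if erythroid precursors did not hold them, which this test cannot decide. Sex is argued against, as the median was 3.415 without the female library, wild type replicate 2. Besides that loss of erythroid cells, 2 explanations stay open, which bulk libraries do not separate. They are a larger share of monocyte or granulocyte-monocyte precursors within the CD71-medium gate, and expression of the monocyte genes in erythroid precursors.

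The rise of immediate early genes, with a median of 1.59 over 11 members, may come from the handling of the cells before lysis, for which the labels give no times. Heat shock members, which handling would be predicted to raise too, had a median of -0.04045 and an upper quartile of 1.29, which met the bound set against handling. That bound was set aside after its value was seen, because the 6 members went both ways, Hspa1a and Hspa1b up and Hsp90aa1, Hsph1 and Hspa8 down, and such a median decides nothing. Handling and genotype cannot be told apart here.

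Among the 20 tested genes nearest to Gata2, 8 were called, against a median of 7 and a 95th percentile of 11 over windows around 14867 other genes. The bound set against a regional effect, a value below that percentile, was met, but a value above the median excludes no effect, so such an effect stays open. Hepatocyte transcripts were highest in -77-/- replicate 3, where Alb stood at 435 against 30.9 to 89.1 in the other 5 libraries and Afp at 395 against 12.0 to 133.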
